A study of Equus caballus with 12 samples.

How the data were processed

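The material was bulk RNA-seq of bone marrow-derived MSCs of 6 horses, each grown as a naive and as a dual-licensed culture for 72 hours, with 1 library per culture. Per the labels' protocols, total RNA was extracted with the RNeasy Mini kit and libraries were made after polyA selection. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.5.2b, counted with featureCounts of Subread 1.5.2 and tested with DESeq2. The version of DESeq2, the genome build, the gene annotation and the use of strand in counting are not given in the sources used here. Without strand information, reads of overlapping genes on opposite strands cannot be told apart. No reference genome was used, so genes are identified by the symbols and Ensembl IDs of the table and no coordinates are given. Of the 1341 genes, 1133 had a symbol and 208 an Ensembl ID only.

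The single table used here was made by the authors. It holds, per gene, the deposited log2 fold change, p-value and adjusted p-value of licensed against naive, and 12 library columns of signal that are read counts divided by 1 size factor per library, here called normalized counts. The p-value and the adjusted p-value are the authors' own. The table lists only genes with an absolute log2 fold change above 1 and an adjusted p below 0.05 (smallest listed absolute log2 fold change 1.001, largest listed adjusted p 0.0499), so genes that did not pass are not analysed here. In the authors' deposited table, the ratio of adjusted p to p fits 13183 tested genes. At that number 89.4% of the ranks come out whole within 0.05, against 17.3% at the next best. These shares are over the listed genes without those of the smallest p-values. The rank of the largest listed p, 5941, leaves 4600 genes past the adjusted p that changed too little to be listed. Each of the 12 sample columns was matched by name to 1 library, and no other column of sample values was present.

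Within each library 100% of the values were whole multiples of 1 step, to within 0.01 reads, so reads per gene could be recovered by division. For the licensed library of horse 1 the step, 1.009721, is near 1, where rounding to whole numbers could be mistaken for it. That 100% of its values were whole multiples of this step argues against rounding. edgeR was also run without that horse. Size factors recovered in this way were 0.9003 to 1.0321 for naive and 0.9778 to 1.1713 for licensed libraries. The reads on listed genes, 1672419 to 3424328 per library, set the counting error, but whole-library depth is unknown. The sum of normalized counts over listed genes was 1.38 to 1.75 times higher in the licensed than in the naive library of the same horse. Recovered reads refitted with DESeq2 1.42.0 gave the deposited log2 fold changes without a term for the horse (0 of 1341 genes differing by more than 0.01), and with the horse 1091 genes differed by more than that.

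Because the table was selected for significance, the authors' calls are the main count. As fixed before the data were examined, limma 3.58.1 (trend and robust empirical Bayes, R 4.3.3) was fitted to log2(normalized count + 1) over all 12 libraries without a term for the horse, with Benjamini-Hochberg adjustment over the 1341 genes, an adjusted p of 0.05 and a 2-fold change, and was used for errors and comparison between horses only. Log2 fold changes given with an SE are from this fit, and on this scale the change of genes with low values is understated, while the deposited log2 fold changes follow the ratio of group means. Named genes are those with the 8 largest deposited rises and falls that have a symbol, moved the same way in all 6 horses and reach a mean of 50 normalized counts in the higher group, the 4 with the highest mean level in each direction under the same conditions, up to 4 listed members with the largest deposited change of each fixed list, and every listed gene of the list of added cytokines and receptors. This gave 83 genes, of which some are not reported here. The rule was first applied with limma's calls and fold changes and then, after that list had been seen, with the authors' calls and deposited fold changes, because the authors' calls are the main count. Other genes that the text names were chosen after their values were seen.

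The 27 gene lists, with 723 distinct genes of which 161 were in the table, were fixed at the same stage. They cover inflammatory cytokines, MSC immunomodulators, NF-κB feedback, TGF-β and SMAD responsive genes, the added cytokines and their receptors, collagens, matrix glycoproteins, metalloproteinases, contractile genes, MHC class I and II, interferon-stimulated genes, complement, cell cycle, MSC surface markers, differentiation genes, growth factors, integrins, lipid synthesis, hypoxia and glycolysis, oxidative stress, immediate early genes and markers of myeloid, lymphoid, endothelial, pericyte and erythroid cells. For each of the 15 lists with at least 3 members in the table, the higher and lower members were set against the higher and lower genes of the rest of the table with Fisher's exact test (two-sided, scipy 1.17.1), with adjustment over the 15 lists. The background is the listed genes, so the test compares directions and not how many members changed. It takes genes as independent units, although all were measured in the same 12 libraries. Its p therefore does not measure variation between horses, and it can be too small where members of a list vary together. Of the 161 listed members, 157 passed limma's adjusted p over all 1341 genes, and in each list the count adjusted over the list alone was the same. Rotation and competitive set tests were not run, as they need the genes that were not listed.

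The 2 libraries of a horse come from the same donor, which pairs them. The deviations of a licensed library from its group mean correlated with those of its own horse's naive library at 0.48 to 0.63 across genes, and with those of any other horse's naive library at 0.14 or less. The fit with the horse as a block was an alternative. The other alternatives were libraries recentred on the median of listed genes, pseudocounts of 0.5 and 10, a minimum mean of 50 normalized counts, an adjusted p of 0.01, a 4-fold change, each horse left out in turn, and DESeq2 on the recovered reads. Added after seeing the data were edgeR 4.0.16 (quasi-likelihood test on recovered reads with the recovered size factors), DESeq2 with the horse, and lists restricted to genes called by limma or edgeR, or by limma without each horse in turn, and the metalloproteinase list without its members of other classes. Every restricted list kept the authors' directions from all 12 libraries, so a restriction changed only which genes were counted. The fits without a term for the horse were tested on simulated reads of the 1341 genes for this comparison, with 100 genes changed 2-fold and 100 changed 4-fold. There limma recovered 48% of the 2-fold and 83% of the 4-fold changes and called 0.61% of the unchanged genes, and edgeR recovered 45% and 82% and called 0.61%. Recovery meant an adjusted p below 0.05 in the right direction, without the 2-fold threshold. The simulated libraries had no horse effect and most of their genes were unchanged, unlike the real table. These rates are therefore not the power or the error rate of the real comparison.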

Results

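Gene expression was measured by bulk RNA sequencing of polyA-selected RNA in mesenchymal stem cells (MSCs), adherent stromal cells that can form bone, cartilage and fat, grown from the bone marrow of 6 horses. Cells of each horse were cultured for 72 hours either in standard medium (naive) or with 2 ng/ml recombinant human IL-1β and 1 ng/ml recombinant human TGF-β2 (dual licensed), which gave 6 naive and 6 licensed libraries paired by donor. IL-1β is an inflammatory cytokine and TGF-β2 a growth factor of matrix production and differentiation. Licensing is the exposure of MSCs to such signals before use. The table used here lists 1341 genes that the authors called different, with a normalized count in each of the 12 libraries. The listed genes held 1672419 to 1844648 reads per naive library and 2718393 to 3424328 per licensed library. These sums are not sequencing depths, because genes that were not listed are not counted in them, and the depth of the whole libraries is unknown.

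The comparison of licensed with naive MSCs asked which genes change their expression when the cytokine pair is added. The authors' deposited table listed 670 genes as higher and 671 as lower in licensed MSCs, each with an adjusted p below 0.05 and a change of more than 2-fold. In the authors' deposited table, 218 genes were at least 4-fold higher and 185 at least 4-fold lower, and 83 were at least 8-fold higher and 48 at least 8-fold lower. Genes of inflammation, NF-κB feedback, collagen synthesis, matrix proteolysis and glucose uptake were among those that rose. The MSC surface marker gene THY1 and the cytoskeletal and nuclear scaffold genes VIM and LMNA were among those that fell. When the listed genes were tested again with limma on the log2 scale, 649 were higher and 627 lower past the same thresholds. This second test repeats a selection already made and is used here for errors and adjusted p-values, not as independent evidence.

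The rises with the largest deposited fold changes were those of ODAPH, GJA5, RHCG, IL6, IL11, FDCSP, CXCL8 and NOS2. ODAPH (ENSECAG00000015736), which encodes a phosphoprotein of enamel mineralisation, went from 1.06 ± 1.14 to 212 ± 93.9 normalized counts (mean ± SD, n = 6 horses), a limma log2 fold change of 6.75 ± 0.41 (SE, adjusted p = 3.81e-08). GJA5 (ENSECAG00000022462), a gap junction connexin, was at 0.517 ± 0.865 normalized counts in naive and 80.5 ± 41.9 in licensed cells. The ammonium transporter gene RHCG (ENSECAG00000008418) rose from 2.92 ± 1.95 to 385 ± 420 normalized counts, and 1 licensed library, that of horse 6, reached 1200. FDCSP (ENSECAG00000004501), a secreted peptide of follicular dendritic cells, rose by 4.80 ± 0.83 on the log2 scale (adjusted p = 1.44e-04). Its log2 fold change was 4.12 without horse 1 and 5.41 without horse 6. Since 1 was added to every value before taking logarithms, these estimates understate the change of genes near 0 in naive cells, and as means of logarithms they can exceed the ratio of means where 1 naive library is far above the others.

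The 8 largest falls were those of MGP, NCCRP1, HPGD, ARHGAP36, PDE1A, SNED1, DDIT4L and SFRP4. HPGD (ENSECAG00000005379), which encodes the enzyme that starts the breakdown of prostaglandins, went from 851 ± 528 to 18.5 ± 12.6 normalized counts, with a log2 fold change of -5.40 ± 0.47 (adjusted p = 8.07e-07). MGP (ENSECAG00000010721), an inhibitor of matrix calcification, went from 389 ± 366 to 7.22 ± 5.23 normalized counts, with individual horses between -6.98 and -2.44 on the log2 scale. The matrix gene SNED1 (ENSECAG00000024612) changed by -5.04 ± 0.54 on the log2 scale and by -5.66 without horse 1. SFRP4 (ENSECAG00000011498), a secreted Wnt antagonist, went from 2550 ± 2150 to 149 ± 110 normalized counts. NCCRP1 (143 ± 102 normalized counts in naive cells), ARHGAP36 (67.4 ± 107), PDE1A (50.3 ± 53.7) and DDIT4L (75.4 ± 67.6) were all below 5 normalized counts on average in licensed cells.

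The genes with the highest mean level in each direction included FN1, COL3A1 and SPARC among those that rose and VIM, CLU, CST3 and LMNA among those that fell. Fibronectin, FN1 (ENSECAG00000000701), rose from 149000 ± 15900 to 408000 ± 89000 normalized counts, and COL3A1 (ENSECAG00000024769) from 48800 ± 12000 to 213000 ± 39500. SPARC (ENSECAG00000013874), a collagen-binding matrix protein, rose by 1.34 ± 0.17 on the log2 scale. Vimentin, VIM (ENSECAG00000004216), went from 242000 ± 21500 to 116000 ± 18000 normalized counts, and LMNA (ENSECAG00000011097), which encodes A-type lamins, from 41300 ± 7740 to 17800 ± 3800. The secreted chaperone clusterin, CLU (ENSECAG00000007010), had a log2 fold change of -1.25 ± 0.19, and the protease inhibitor cystatin C, CST3 (ENSECAG00000038893), of -2.25 ± 0.24. The limma adjusted p-values of these 7 genes lay at or below 6.43e-05.

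Inflammatory cytokine genes made up several of the largest rises. Of 37 cytokines and chemokines on the fixed list, 8 were listed, 7 as higher and 1 as lower. IL11 (ENSECAG00000014511) rose from 1040 ± 417 to 46100 ± 17900 normalized counts (log2 fold change 5.50 ± 0.34, adjusted p = 3.81e-08), and IL6 (ENSECAG00000016482) from 131 ± 234 to 6730 ± 6820 (6.24 ± 0.79, adjusted p = 1.17e-05). The neutrophil chemoattractant CXCL8 (ENSECAG00000015342) rose from 42.2 ± 71.7 to 1630 ± 1340 normalized counts. CSF3 (ENSECAG00000008668), the granulocyte growth factor, rose by 3.81 ± 0.84 on the log2 scale and by 3.21 without horse 3. CXCL6, LIF and IL23A were the other listed members that rose, and IL34, a ligand of the macrophage growth factor receptor, was the member that fell. Against the rest of the table, the split of 7 to 1 did not pass Fisher's exact test after adjustment over 15 lists (two-sided, p = 0.0384, adjusted p = 0.115).

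All 12 listed members of the NF-κB feedback and signalling list, out of 26, were higher in licensed cells, a split that differed from that of the other listed genes (Fisher's exact test, two-sided, adjusted p = 0.00345). As for every list, this test takes genes as independent units, and its p does not measure variation between horses. TNFAIP3 (ENSECAG00000009626), a deubiquitinase that limits NF-κB signalling, rose from 76.7 ± 158 to 1350 ± 893 normalized counts (log2 fold change 5.67 ± 0.81, adjusted p = 3.18e-05). In the authors' deposited table its log2 fold change was 4.14, on the scale of the ratio of group means, where the naive mean includes the high level of horse 1. ZC3H12A (ENSECAG00000009562), a ribonuclease that degrades cytokine mRNA, rose by 3.30 ± 0.28, and IER3 (ENSECAG00000017157), an immediate early gene, by 3.27 ± 0.32. TNIP3 (ENSECAG00000010953), a partner of the TNFAIP3 protein, rose from 3.36 ± 5.66 to 30.2 ± 16.4 normalized counts. Restricted to genes changed at least 4-fold, 6 members of this list remained, all higher, and the adjusted p was 0.189, against 0.00245 to 0.0145 in the other alternatives. These alternatives kept the authors' directions from all libraries, so no member could turn lower in any of them.

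**Figure D1:**
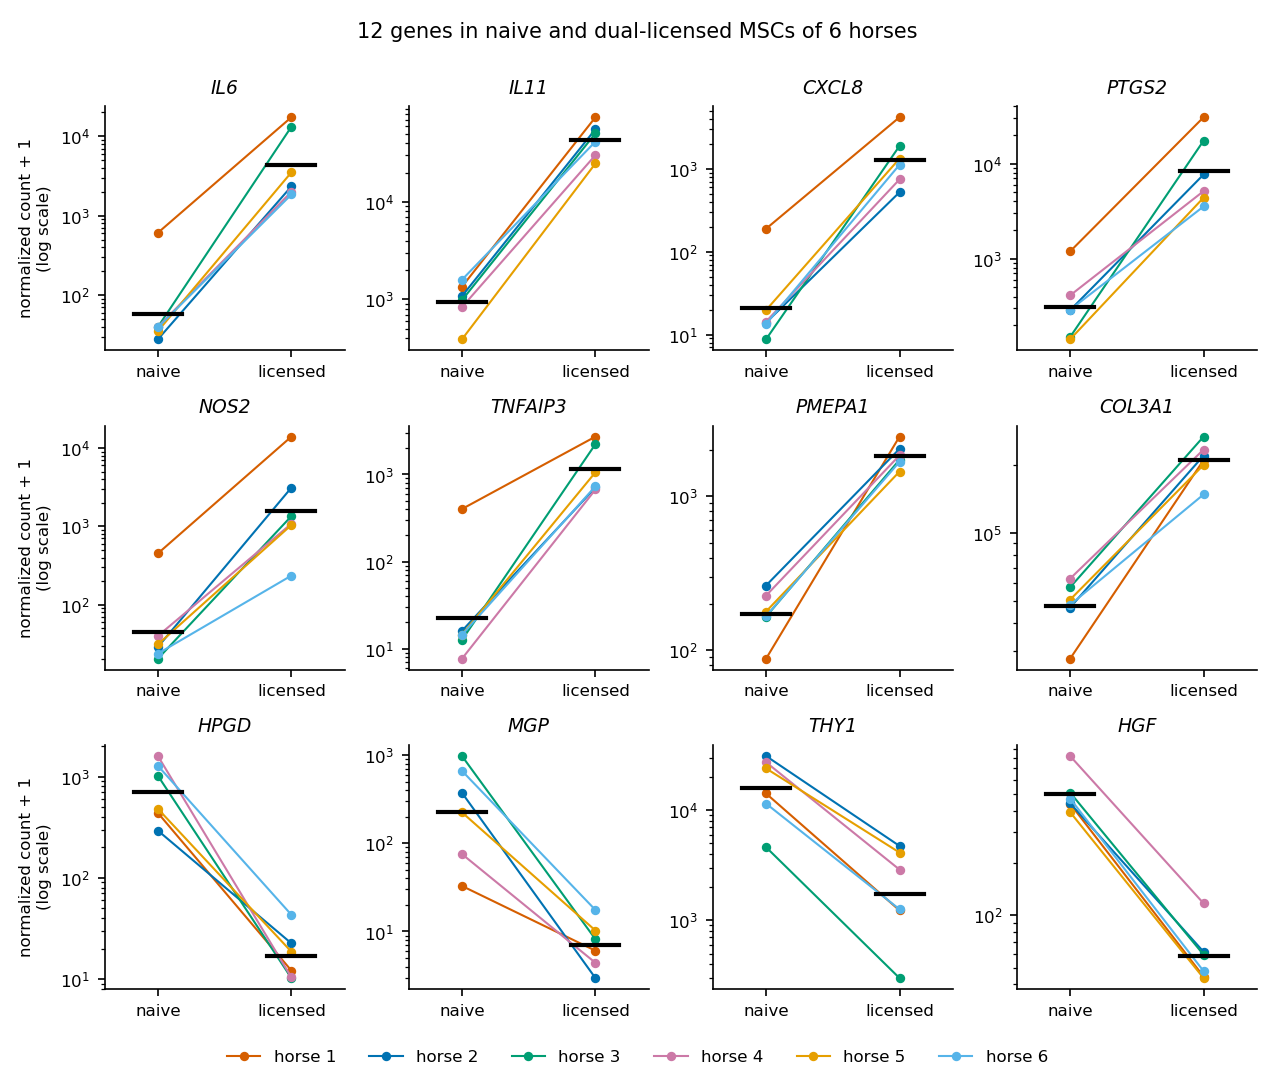
Normalized counts plus 1 (log scale) of 12 genes in naive and licensed MSCs, with each line joining the 2 libraries of 1 horse and each black bar the geometric mean of count plus 1 over 6 horses. In all 12 panels the lines of the 6 horses run in the same direction, and horse 1 started from higher naive levels of IL6, CXCL8, PTGS2, NOS2 and TNFAIP3 than the other 5 horses.

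Secreted and surface mediators of MSC immunomodulation moved in both directions. Of 26 such genes, 7 were listed as higher and 3 as lower, which did not differ from the rest of the table (Fisher's exact test, two-sided, adjusted p = 0.433). PTGS2 (ENSECAG00000017181), the inducible cyclooxygenase of prostaglandin synthesis, rose from 411 ± 395 to 11500 ± 10700 normalized counts (log2 fold change 4.75 ± 0.60, adjusted p = 1.16e-05). The inducible nitric oxide synthase gene NOS2 (ENSECAG00000024761) rose by 5.15 ± 0.92 and TNFAIP6 (ENSECAG00000012104), a hyaluronan-binding anti-inflammatory protein, by 2.76 ± 0.52. ARG2, HMOX1, STC1 and STC2 were the other members that rose. HGF (ENSECAG00000011223), the hepatocyte growth factor, went from 511 ± 158 to 61.3 ± 27.9 normalized counts (-3.09 ± 0.27, adjusted p = 7.82e-07), and VSIR and LGALS3 also fell.

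The 2 libraries of horse 1 stood apart from the others in these gene groups. The naive library of horse 1 was above all other naive libraries for 14 of the 19 inflammatory and NF-κB members that rose, while no other naive library was highest for more than 3 of them. Its TNFAIP3 level was 400 normalized counts against 6.66 to 15 in the other 5 naive libraries, its SOD2 level 38500 against 1650 to 2760, and its IL6 level 609 against 26.8 to 38.9. Its CXCL6 level, 882, lay within the range of 455 to 1470 of the other naive libraries. The licensed library of horse 1 was above the other licensed libraries for 12 of the 19 genes. Among the 651 other listed genes that rose, horse 1 was highest for 200 in naive and 242 in licensed cells. On the second principal component of the listed genes, which carried 10.7% of their variance, the naive and licensed libraries of horse 1 lay at 37.52 and 23.12 and the other 10 libraries between -13.49 and 1.32. Without horse 1, limma called 599 genes higher and 627 lower.

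**Figure D2:**
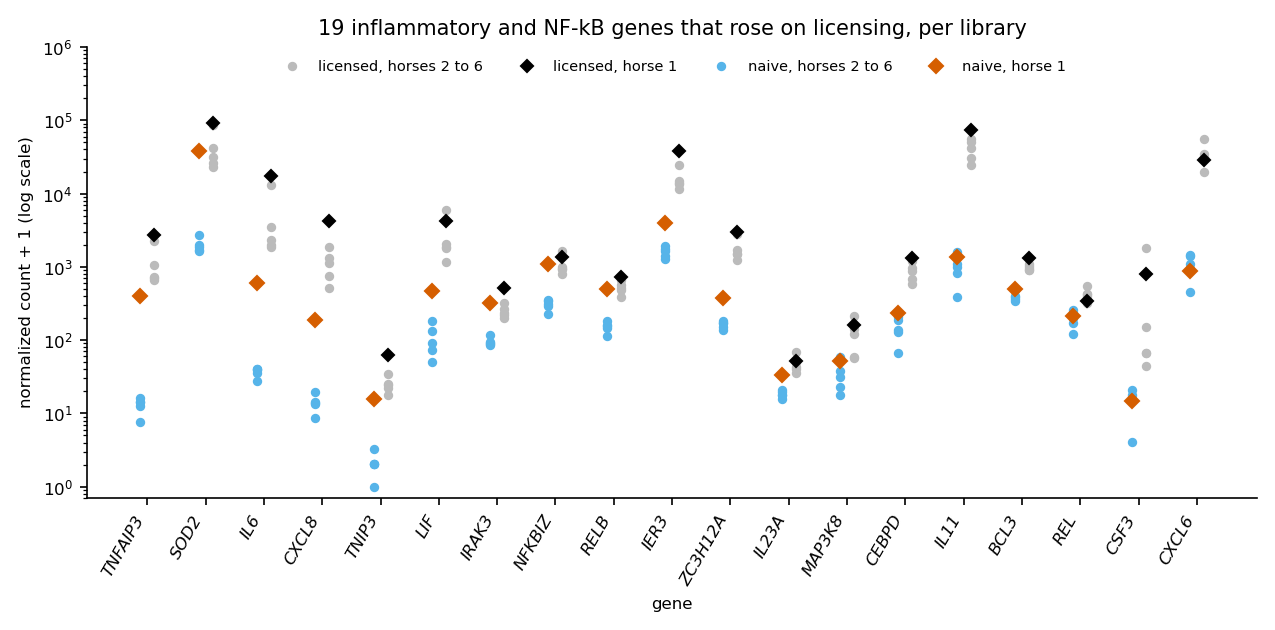
Normalized counts plus 1 (log scale) of the 19 listed inflammatory and NF-κB genes that rose, with 1 symbol per library, diamonds for horse 1 and circles for horses 2 to 6, and genes ordered by the excess of the naive library of horse 1. The naive library of horse 1 lay above the other 5 naive libraries for 14 of the 19 genes, with TNFAIP3 at 400 against at most 15 normalized counts.

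TGF-β and SMAD responsive genes were listed in both directions, 9 higher and 6 lower of 32 on the list (Fisher's exact test, two-sided, adjusted p = 0.678). The list was fixed without an expected direction for each member, so this test cannot tell whether a TGF-β response was present. PMEPA1 (ENSECAG00000018005), a feedback inhibitor of TGF-β signalling, rose from 180 ± 60.1 to 1860 ± 346 normalized counts (log2 fold change 3.42 ± 0.24, adjusted p = 1.38e-07), and INHBA (ENSECAG00000022448), an activin subunit, from 754 ± 286 to 5490 ± 1330. IGFBP5 (ENSECAG00000013425) rose by 2.85 ± 0.78 on the log2 scale (adjusted p = 0.00372). BAMBI (ENSECAG00000003193), a decoy receptor of the TGF-β family, went from 146 ± 72.7 to 30.2 ± 26.3 normalized counts (-2.31 ± 0.70, adjusted p = 0.00693). The other members listed as lower were ID1, ID4, SMAD6 and SNAI2, which passed limma's test, and IGFBP3, which did not (log2 fold change -1.06 ± 0.61, adjusted p = 0.106, and 0.0346 with the horse as a block). The added cytokines and their receptors had 2 of 18 genes in the table. The IL-1 receptor gene IL1R1 (ENSECAG00000016394) went from 464 ± 137 to 948 ± 368 normalized counts and the TGF-β co-receptor gene TGFBR3 (ENSECAG00000019700) from 2060 ± 535 to 419 ± 85.7 (-2.28 ± 0.20, adjusted p = 9.67e-07).

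Of 43 collagen genes and genes of collagen processing, 12 were in the table, 11 listed as higher and 1, the lysyl oxidase gene LOXL3, listed as lower (Fisher's exact test, two-sided, adjusted p = 0.0230). COL5A1 (ENSECAG00000042356) rose from 13500 ± 4390 to 70500 ± 18000 normalized counts, COL4A1 (ENSECAG00000019838) by 1.80 ± 0.25 on the log2 scale, and PLOD2 (ENSECAG00000009297), which hydroxylates collagen lysines, from 8430 ± 951 to 33800 ± 5990. Matrix glycoproteins and proteoglycans were listed as 12 higher and 7 lower of 48 (adjusted p = 0.433). COMP (ENSECAG00000000336), a cartilage matrix protein, rose by 3.27 ± 0.32 and the microfibril gene MFAP4 (ENSECAG00000013301) by 2.85 ± 0.28 on the log2 scale. EFEMP1 (ENSECAG00000010447), a fibulin, went from 2900 ± 627 to 411 ± 174 normalized counts. Of the members listed as lower, ASPN and OGN did not pass limma's test without a term for the horse (adjusted p = 0.123 and 0.0701) and passed it with the horse as a block (0.0197 and 4.56e-06). Counting only genes that moved the same way in all 6 horses, the collagen list had 10 higher and 1 lower member and an adjusted p of 0.0569. Restricted to genes changed at least 4-fold, it had 3 members, all higher, a split that could not be more one-sided, and an adjusted p of 0.506. With genes called by limma without horse 2, 3, 4 or 6, its adjusted p was 0.0748, 0.0588, 0.0873 and 0.0744, and the other alternatives gave 0.0229 to 0.0432.

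The list of metalloproteinases, their inhibitors and a few other matrix proteolysis genes had 10 higher and 1 lower of 37 (Fisher's exact test, two-sided, adjusted p = 0.0230). Without its members of other classes, of which the serine protease gene PLAU and its receptor gene PLAUR were listed, it had 8 higher and 1 lower and missed the threshold (adjusted p = 0.0782). ADAM12 (ENSECAG00000012744) rose from 877 ± 338 to 7260 ± 1520 normalized counts and the aggrecanase gene ADAMTS4 (ENSECAG00000024172) from 175 ± 42.1 to 1340 ± 456 (log2 fold change 2.90 ± 0.22, adjusted p = 2.84e-07). The macrophage elastase gene MMP12 (ENSECAG00000019445) was higher in 5 of 6 horses, with a log2 fold change of 1.92 ± 0.74 (adjusted p = 0.0236) that lost limma's threshold without horse 1, 4 or 6 (adjusted p = 0.0953, 0.0573 and 0.0637). ADAMTS15 (ENSECAG00000015715), the member that was lower, had a log2 fold change of -1.83 ± 0.71 (adjusted p = 0.0247) and lost the threshold without horse 2, 3 or 5 (adjusted p = 0.0515, 0.0719 and 0.0984). With the horse as a block, the adjusted p was 0.00426 for MMP12 and 0.00167 for ADAMTS15. With genes called by limma without horse 1, the list had 6 higher and 1 lower member (adjusted p = 0.179), and without horse 4 or 6 it also missed the threshold (adjusted p = 0.146 and 0.0744). The threshold was also missed among genes that moved the same way in all 6 horses (8 higher and 1 lower, adjusted p = 0.144) and among genes changed at least 4-fold (4 higher and 1 lower, adjusted p = 0.634), while the other alternatives gave 0.0136 to 0.0432.

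Contractile and myofibroblast genes divided evenly, with 3 higher and 3 lower of 20 (adjusted p = 1). FAP (ENSECAG00000011790), a membrane protease of activated fibroblasts, rose from 829 ± 320 to 4350 ± 1140 normalized counts and CNN1 (ENSECAG00000014489), calponin, by 1.59 ± 0.36 on the log2 scale. The smooth muscle myosin gene MYH11 (ENSECAG00000017015) had a log2 fold change of -2.64 ± 0.34 and the actin-bundling gene SYNPO2 (ENSECAG00000018218) of -1.89 ± 0.51. Integrins, cadherins and other adhesion genes were listed as 3 higher and 2 lower of 30 (adjusted p = 0.937). The integrin genes ITGB3 (ENSECAG00000017625) and ITGA5 (ENSECAG00000024979) rose by 2.09 ± 0.13 and 1.63 ± 0.18, and the cadherin gene CDH13 (ENSECAG00000021162) had a log2 fold change of -1.64 ± 0.32. ITGA10 (ENSECAG00000008533), a collagen-binding integrin, had a log2 fold change of -1.79 ± 0.75 (adjusted p = 0.0335), which lost limma's threshold without horse 3, 4, 5 or 6 (adjusted p = 0.0749, 0.0809, 0.0590 and 0.0741). It was lower in 6 of 6 horses, and with the horse as a block its adjusted p was 4.71e-06.

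**Figure D3:**
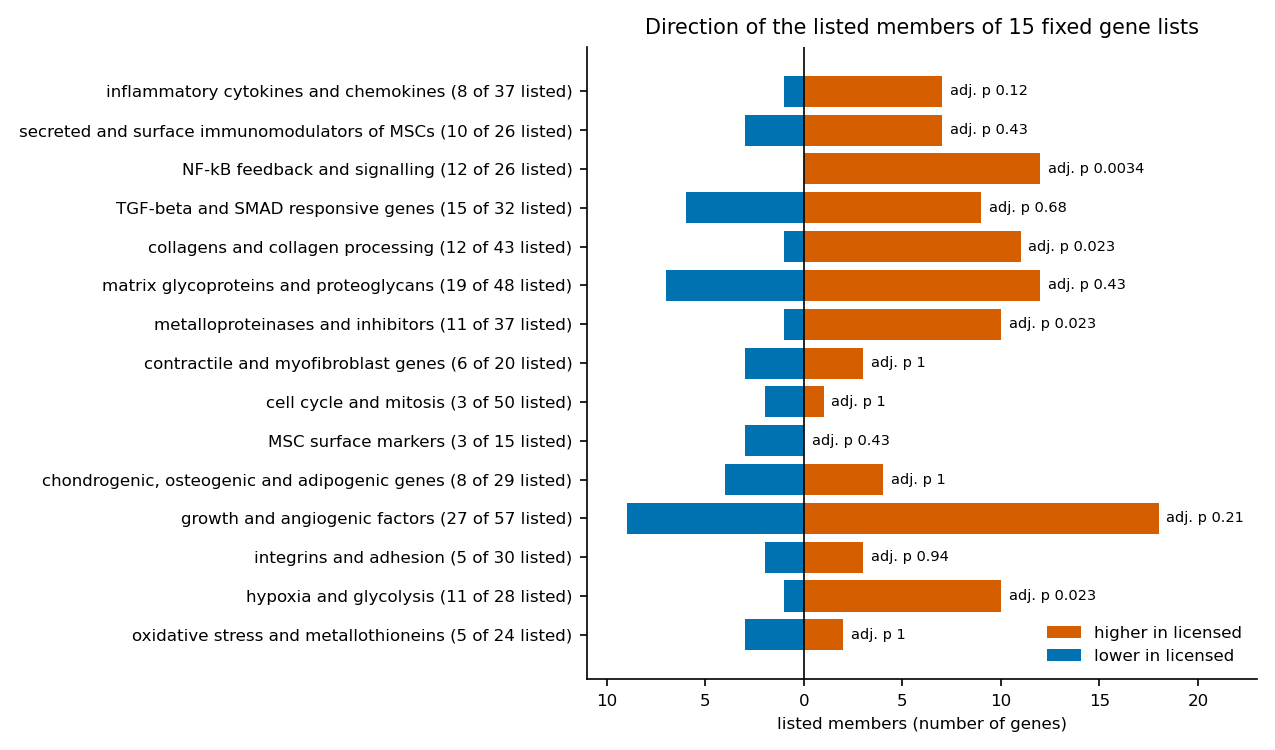
Number of listed members higher (right) and lower (left) in licensed than in naive MSCs for the 15 fixed gene lists with at least 3 listed members, with the adjusted p of Fisher's exact test beside each bar. The NF-κB list had 12 members higher and 0 lower, and the collagen, metalloproteinase and hypoxia and glycolysis lists each had an adjusted p of 0.0230.

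Genes of hypoxia and glycolysis were listed as 10 higher and 1 lower of 28 (Fisher's exact test, two-sided, adjusted p = 0.0230). Hexokinase, HK2 (ENSECAG00000021905), rose from 445 ± 221 to 3540 ± 1050 normalized counts (log2 fold change 3.05 ± 0.27, adjusted p = 9.19e-07), and the glucose transporter gene SLC2A1 (ENSECAG00000000303) from 1080 ± 167 to 8660 ± 3740. BNIP3 (ENSECAG00000017458), a mitophagy receptor, rose by 2.21 ± 0.31, and PFKFB3 (ENSECAG00000012172), a regulator of glycolytic flux, by 1.76 ± 0.26. PDK4, which restrains pyruvate oxidation, was the member that fell. Naive levels of HK2 and BNIP3 were highest in horse 1, at 880 and 7080 normalized counts against at most 454 and 3670 in the other horses. Counting only genes that moved the same way in all 6 horses, the adjusted p of this list was 0.0569. Among genes changed at least 4-fold, where its 3 members were all higher, it was 0.506. With genes called by limma without horse 2, 3, 4 or 6, it was 0.0748, 0.147, 0.107 and 0.0744, and the other alternatives gave 0.0229 to 0.0460.

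Growth and angiogenic factors had the most listed members, 18 higher and 9 lower of 57, a split that did not differ from the rest of the table (Fisher's exact test, two-sided, adjusted p = 0.210). The receptor ligand NRG1 (ENSECAG00000021343) rose from 9.78 ± 9 to 142 ± 98.7 normalized counts, and FGF1 (ENSECAG00000020769) from 19 ± 5.22 to 248 ± 89.6. SFRP4 and HGF had the lowest log2 fold changes of the list.

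Further metabolic and stress genes moved singly. The fatty acid desaturase genes FADS1 (ENSECAG00000023280) and FADS2 (ENSECAG00000024650) rose by 2.56 ± 0.14 and 2.67 ± 0.20 on the log2 scale and were the only 2 of 29 cholesterol and lipid synthesis genes in the table. Of 24 genes of oxidative stress, 2 were listed as higher and 3 as lower (adjusted p = 1). SOD2 (ENSECAG00000011797), the mitochondrial superoxide dismutase, rose from 8080 ± 14900 to 50300 ± 31100 normalized counts, with horse 1 highest in naive cells, and HMOX1 (ENSECAG00000001129), heme oxygenase, by 1.35 ± 0.30 on the log2 scale. Catalase, CAT (ENSECAG00000019408), went from 5920 ± 1510 to 1550 ± 165 normalized counts and the extracellular dismutase gene SOD3 (ENSECAG00000035543) from 48.3 ± 24.4 to 5.24 ± 1.91. Of 50 cell cycle genes, 3 were listed. CCNE2 (ENSECAG00000020270) rose by 1.00 ± 0.17, and CCND2 (ENSECAG00000012663) and TYMS (ENSECAG00000023203) had log2 fold changes of -1.31 ± 0.25 and -1.16 ± 0.15. Of 26 complement and acute phase genes, ceruloplasmin, CP (ENSECAG00000012064), rose by 1.20 ± 0.33, and CLU fell. Of 20 immediate early and heat shock genes, GADD45B (ENSECAG00000009168) rose by 1.20 ± 0.18 and FOS (ENSECAG00000014260) had a log2 fold change of -1.04 ± 0.22.

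The 3 listed MSC surface markers, of 15, were lower in licensed cells (Fisher's exact test, two-sided, p = 0.249, adjusted p = 0.433). With 3 members no split can be more one-sided, so this test could not have passed its threshold. THY1 (ENSECAG00000009966), a marker used to define MSCs, went from 18800 ± 10300 to 2430 ± 1780 normalized counts (log2 fold change -3.19 ± 0.65, adjusted p = 4.85e-04). MCAM (ENSECAG00000013036), an adhesion molecule of perivascular cells, and the tetraspanin gene CD9 (ENSECAG00000003002) had log2 fold changes of -1.34 ± 0.25 and -1.33 ± 0.13. Chondrogenic, osteogenic and adipogenic genes divided evenly, with 4 higher and 4 lower of 29 (adjusted p = 1). ADIPOQ (ENSECAG00000002962), adiponectin, rose from 3.44 ± 2.13 to 85.7 ± 40.6 normalized counts, while the adipogenic transcription factor gene CEBPA (ENSECAG00000032515) went from 1520 ± 339 to 151 ± 77.1. Bone sialoprotein, IBSP (ENSECAG00000024478), rose by 2.53 ± 1.09 (adjusted p = 0.0382) and lost limma's threshold without horse 2, 3, 4 or 6 (adjusted p = 0.103, 0.106, 0.0657 and 0.0623). With the horse as a block, that is, with the 2 libraries of each horse compared within the pair, its adjusted p was 3.97e-05, the lowest of its alternatives.

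Marker genes of other cell types were rarely in the table. Of 20 myeloid markers only S100A12 (ENSECAG00000009742) was listed, at 24.3 ± 13.6 normalized counts in naive and 111 ± 45.1 in licensed cells. Of 14 endothelial markers only the transcription factor gene ERG (ENSECAG00000010667) was listed, with a log2 fold change of 1.41 ± 0.24. The 2 listed of 10 pericyte and smooth muscle markers were MCAM and MYH11, described above. No gene of the lymphoid (18 genes), erythroid and megakaryocyte (12), MHC class I (14), MHC class II (19) or interferon-stimulated (46) lists was in the table. A gene that is not listed was either not tested, not past the adjusted p or changed by less than 2-fold, and is not shown to be unchanged.

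The last comparison was between horses. For 1258 of the 1341 listed genes, licensed minus naive had the deposited direction in all 6 horses, for 74 in 5 and for 9 in 4. Of the 83 named genes, 82 moved the same way in all 6 horses, and MMP12 in 5. These counts are largely fixed by selection, because the genes were listed for a difference between the same groups and part of the naming rule required 6 of 6 horses. For a gene with 6 of 6 horses in 1 direction, the exact sign-flip permutation test gives p = 0.0312 (two-sided), which is the smallest p that 6 pairs allow and, after that selection, no evidence of its own. The median difference over genes listed as higher was 1.53 to 1.77 per horse on the log2 scale, and over genes listed as lower -1.63 to -1.39. Horse 1 was the horse farthest from the median of the 6 for 34.6% of listed genes and horse 3 for 24.5%, against 9.3% to 11.9% for each of the other horses. Horse 1 moved against the call for 37 genes and each of the others for 4 to 16.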

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

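All the tests of explanations in this part were chosen after the result they concern had been seen. Among the 83 named genes, 20 had 1 naive library far from the other 5, with a gap to its nearest neighbour that exceeded Dixon's 95% critical value, and 12 of these were the library of horse 1. For normally distributed and independent values, chance flags about 1 in 20 groups, or 4.2 of 83. Counts near 0 and genes that vary together depart from this, so 4.2 is only a rough guide. The naive library of horse 1 was highest for IL6 (609 normalized counts against 26.8 to 38.9), CXCL8 (188 against 7.75 to 18.7), NOS2 (450 against 19.4 to 38.9), PTGS2 (1190 against 141 to 410), TNFAIP3 (400 against 6.66 to 15), ZC3H12A (369 against 136 to 184), IER3 (3910 against 1260 to 1900) and TNIP3 (14.8 against 0 to 2.22). It was also highest for SOD2 (38500 against 1650 to 2760), HK2 (880 against 272 to 454), BNIP3 (7080 against 1800 to 3670) and HMOX1 (4810 against 2040 to 3060).

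Licensed RNA or cells mixed into that library would raise every gene that licensing raised by 1 share. No share of any of the 6 licensed libraries placed all 19 inflammatory and NF-κB genes that rose. The best share left 31.6% of them (6 genes) outside a band from 0.5 times the lowest to 2 times the highest of the other naive libraries, widened by 3 counting errors, while 0 genes of each of the other 5 naive libraries lay outside a like band of the remaining 4, without horse 1 and without mixing. This argues against mixing as the only cause, but weakly, since the test was run in 3 forms and the limits of the last were set after the values of the others had been seen. In the first form, 35.5% of 62 genes raised at least 8-fold stayed below the level of the median share, and in the second the band was not widened and 42.1% of the 19 genes were left outside it, against 5.3% to 15.8% in the other naive libraries. Both were undecided under the limits then set. In horse 1, the apparent share of a gene is its naive excess over the other naive median, as a percent of its licensed excess. Its median was 5.2% for 10 inflammatory and NF-κB members changed at least 8-fold (-0.8% to 22.8%). For 52 other genes changed at least 8-fold it was 0.3% (quartiles -2.0% and 4.7%). For these genes the unequal shares also argue against mixing as the only cause, although the spreads overlap. A smaller share of licensed material together with another cause stays open. Swapped labels of the 2 horse 1 libraries are argued against by the 97.2% of listed genes that moved in the called direction in horse 1. Cells of another type could not be tested, with 1 myeloid marker in the table, since a test needed 3. A difference in the donor or its culture, with 1 culture per horse and condition, remains open, and no biological explanation was tested.

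Of the licensed libraries, 17 values lay apart, 8 of them in horse 1. Those of horse 1 included CXCL8 (4200 normalized counts against 521 to 1890), NOS2 (14000 against 234 to 3120), TNIP3 (61.6 against 17.1 to 33.7), CLU (53700 against 24200 to 31300), PFKFB3 (32200 against 10600 to 14500), LMNA (10200 against 18000 to 20500) and CNN1 (965 against 2470 to 3210). Horse 3 stood apart for IL1R1 (1670 against 684 to 933) and ADAMTS4 (2200 against 1010 to 1450), among others. Horse 6 did so for RHCG (1200 against 62.4 to 390) and HPGD (42.1 against 9.20 to 21.5), horse 2 for PDE1A (7.82 against 0 in each of the others) and BAMBI (80.2 against 4.04 to 30.5), and horse 4 for HGF (116 against 42.5 to 60.6) and FOS (2670 against 1160 to 1630).

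The other naive values that lay apart were those of ODAPH in horse 5 (3.12 normalized counts against 0 to 1.11), FDCSP in horse 4 (15.6 against 0 to 5.16), ARHGAP36 in horse 2 (277 against 7.41 to 80.4), CSF3 in horse 6 (3.10 against 13.8 to 19.7), HGF in horse 4 (823 against 391 to 507), IL1R1 in horse 3 (739 against 380 to 450), MYH11 in horse 5 (240 against 98.8 to 150) and CCNE2 in horse 3 (149 against 102 to 117). HGF in horse 4 and IL1R1 in horse 3 were thus high in both libraries of the same animal.

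The difference between the 2 libraries of a horse lay apart for 7 genes, against 4.2 by chance if values were normally distributed and independent. On the log2 scale, horse 1 had a larger rise of PMEPA1 (4.80 against 2.96 to 3.39) and ADAM12 (4.21 against 2.79 to 3.13) and a deeper fall of CD9 (-1.64 against -1.33 to -1.20). Horse 3 had a larger rise of ZC3H12A (4.06 against 2.99 to 3.29), IER3 (4.27 against 2.80 to 3.35) and HK2 (4.06 against 2.53 to 3.05), and horse 4 of SPARC (1.61 against 1.25 to 1.32).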

How the results depend on the processing

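The edgeR fits, DESeq2 with the horse, the lists restricted by limma or edgeR, the metalloproteinase list without other classes and the limit for the splits of libraries were chosen after seeing the data. With the horse as a replicate block, limma called 655 genes higher and 641 lower, against 649 and 627 without it, the 4 lists past their threshold stayed past it, and the 83 named genes kept an adjusted p below 0.05. Counts stayed within 1.5 times of the main ones under every setting except 4-fold, which by its construction left 218 higher and 185 lower of the authors' calls and 216 and 164 in limma. Every fit was run on the 1341 genes already selected in the same 12 libraries. Stable counts were thus largely fixed beforehand and are no evidence of their own. Leaving out 1 horse gave 599 to 623 higher and 578 to 627 lower genes. Recentring the libraries (median shift -0.056) gave 660 and 587, and pseudocount 10 gave 538 and 515. Of the 1341 genes, 1258 moved alike in 6 horses with pseudocount 10 and 1254 after recentring, against 1258. On recovered reads, DESeq2 without the horse called 670 and 671, edgeR 669 and 671, and edgeR without horse 1 618 and 639. That DESeq2 fit repeats the authors' own. Among genes changed at least 4-fold, the NF-κB, collagen and hypoxia and glycolysis lists kept only higher members. Their splits could not be more one-sided there, so a lost threshold does not show weaker agreement in direction. Of the 4 gene lists past the threshold, each lost it among these genes, where fewer genes were tested (NF-κB adjusted p = 0.189, collagens 0.506, metalloproteinases 0.634, hypoxia and glycolysis 0.506). Among genes that moved alike in all 6 horses, collagens (0.0569), hypoxia and glycolysis (0.0569) and metalloproteinases (0.144) missed it, and with genes called by limma without single horses so did collagens (without horse 2, 3, 4 or 6: 0.0748, 0.0588, 0.0873 and 0.0744), hypoxia and glycolysis (without the same horses: 0.0748, 0.147, 0.107 and 0.0744) and metalloproteinases (without horse 1, 4 or 6: 0.179, 0.146 and 0.0744), in each case with fewer samples. Metalloproteinases and inhibitors without the members of other classes had 8 higher and 1 lower (0.0782). The NF-κB list stayed past it with genes called by limma without any 1 horse (0.00245 to 0.0145). All restricted lists kept the authors' directions from all 12 libraries. Their values thus show which members stayed called, and not whether a split of directions holds without a horse. Of the 83 named genes, MMP12, ADAMTS15, IBSP and ITGA10 lost limma's threshold when single horses were left out (14 values, against 733 over all settings that kept their side), and no setting that was run reversed a direction. The limma fits with a horse left out had no term for the horse. In limma with the horse as a block and all 6 horses, these genes had adjusted p-values of 0.00426, 0.00167, 3.97e-05 and 4.71e-06. No blocked fit was run with a horse left out. For ITGA10 and IBSP, all 6 horses moved the same way (-2.36 to -1.36 and 1.30 to 3.90 on the log2 scale). Where they lost the threshold, their log2 fold changes were -1.87 to -1.67 and 2.25 to 2.69, against -1.79 and 2.53 with all horses. These values argue against dependence of these 2 changes on a single horse. For MMP12 (horses at -0.27 to 4.18) and ADAMTS15 (-3.68 to -0.15), such dependence and the ignored pairing cannot be told apart. The setting without a filter is the main one here, and TMM was not run, because whole-library counts were not used here. In 100 of the 462 possible splits of the 12 libraries, only the real split gave as many calls as 1276, and the highest other, which kept 10 libraries on their real side, gave 582. Among the 32 splits that part every pair, the highest other gave 0. Since the genes were listed for differing between the real groups, these splits cannot exclude chance. Depth limits genes with few reads, and 2 to 19 listed genes were at 0 in each library.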

Other observations

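Gene groups in this part were put together after the values had been seen, so their directions are descriptions and not tests of a theme. All 7 listed genes of the interleukin 6 family and its signalling rose, in all 6 horses. OSM, a cytokine of that family, went from 11.8 ± 20.7 to 353 ± 371 normalized counts (SD, n = 6), with horse 1 at 54 against 2.07 to 4.44 in naive and at 1090 against 108 to 376 in licensed cells. LIF went from 166 ± 156 to 2850 ± 1890, with horse 1 at 469 against 49.6 to 181 in naive cells, and the receptor gene OSMR rose by 1.05 on the log2 scale. The 4 listed ligands of the EGF family, NRG1, EREG, AREG and HBEGF, rose by 2.39 to 4.09. All 7 listed genes grouped here under iron and zinc handling were higher, with HMOX1 and CP, already counted in lists above, among them. The transferrin receptor gene TFRC went from 1950 to 16900 normalized counts (log2 fold change 3.08). The zinc and iron importer gene SLC39A14 and the ferritin gene FTH1 also belonged to this group. Of 8 listed clock genes, ARNTL, NPAS2, RORA, NFIL3 and BHLHE40 rose, while PER3, DBP and HLF fell, HLF in 5 of 6 horses.

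Of 14 listed slits, netrins, semaphorins, ephrins and their receptors, 11 fell and 3 rose, each in all 6 horses. SLIT3 went from 2900 to 401 and SLIT2 from 4600 to 1320 normalized counts, whereas SEMA7A rose from 1130 to 3870. Of 6 listed S100 genes, 5 fell, with S100A4 at 26900 in naive and 6340 in licensed cells, and S100A12 rose. Of 6 listed desmosome genes, 3 rose and 3 fell. The desmosomal cadherin genes DSG2 and DSC2 and the plakin gene DSP rose from low levels, while PPL, another plakin gene, went from 5580 to 542 normalized counts, and EVPL and PKP1 had log2 fold changes of -1.32 and -2.21. Of 8 listed BMP pathway genes, 2 rose and 6 fell. BMP2 rose from 384 to 4250 and the receptor gene BMPR1B from 1.62 to 21.2 normalized counts, and BMP4, ID1, ID4, SMAD6, ATOH8 and BAMBI fell in all 6 horses. Of these, ID1, ID4, SMAD6 and BAMBI were already counted in the TGF-β and SMAD list above. Of 4 listed prostaglandin genes, PTGS2 and the phospholipase genes PLA2G4A and PLA2G3 rose and HPGD fell.

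Both libraries of horse 1 were low in IBSP, ALPL and DLX5, genes of the osteoblast lineage that were picked after their values were seen. Other genes of that lineage were not counted. IBSP was at 19.1 normalized counts in the naive and 48.5 in the licensed library of horse 1, against 140 to 976 and 1280 to 5940 in the other horses. ALPL was at 501 and 2150 against 2980 to 7050 and 9730 to 23700, and DLX5 at 144 and 96.9 against 1080 to 1330 and 398 to 584. TGM2, a transglutaminase gene, was at 10100 in the naive library of horse 1 against 341 to 1230, and at 105000 in its licensed library against 19300 to 38700.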
